A study of Homo sapiens with 9 samples.

How the data were processed

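RNA was measured by sequencing in Huh7, a human hepatocellular carcinoma cell line, in 3 groups of 3 samples each. Per the labels' protocols, ectosomes, vesicles shed from the cell surface, were prepared from the medium of LX-2, a human hepatic stellate cell line, cultured for 36 h in medium with 10% fetal bovine serum. The medium was spun at 300 g to remove cells and at 2000 g to remove debris, and the ectosomes were pelleted at 16500 g for 30 min. Huh7 cells received ectosomes or none for 12 h, followed by fresh medium for 12 h, before RNA extraction. The series title names TGF-β-treated stellate cells as the source of the ectosomes. Groups were taken from the sample titles: control, ectosome, and ectosome from cells with HK1 knocked down, written here as HK1-KD ectosome. The series' design text calls the samples of a group independent, without saying whether they came from separate cultures. The p-values of single genes therefore measure the spread between these samples.

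The deposited values are FPKM, fragments per kilobase of exon, scaled to the library total, one column per sample. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and the genome build GRCh38 were used; the annotation, the strand setting and the rule for choosing rows are not given in the sources used here. Both deposited tables hold the same 10000 rows in the same order, sorted by their mean over the 9 samples, and the lowest row mean is 2.30 FPKM. The ectosome columns of the tables are identical, so all 9 samples stand on 1 normalization. Genes outside these rows were not analysed here, and the filter of a mean of at least 1 FPKM removed no row.

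The reads behind the values were recovered as a check. With exon lengths from GENCODE release 29 on GRCh38, 9935 rows matched 1 annotated gene each, and 100.0% of their values in every library came out as whole reads within a tolerance of 0.05. The other 65 rows included 24 with a repeated name and 14 named as calendar dates; they were kept under the names in the tables and have no coordinates. The implied library totals lay between 17773140 and 27230636 reads, of which 96.0 to 96.9% fell in the matched rows. The median row held 798 to 1219 reads per library, so sampling noise was small for most rows. Genes whose exons overlap another gene are less certain, because the strand setting is unknown: among the genes named, these include ICAM1, CXCL6, DTX3L, HMGCS1, APOA1, BHLHE40, FADS2, IDI1, HK2, GPI and SLC16A3. SOD2 was among the rows without a match.

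Genes were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend, two-sided, and called at a Benjamini-Hochberg adjusted p under 0.05. A fold change on this scale understates the change of low genes. Ectosome against control and HK1-KD ectosome against ectosome were each fitted on their 6 samples, and HK1-KD ectosome against control on all 9 samples. Of 45 gene lists fixed in advance, the 41 with at least 5 measured members were tested with limma's camera at its preset correlation of 0.01. Camera with an estimated correlation and fry, in its directional form, were alternatives. Counts adjusted over the list alone applied Benjamini-Hochberg to the members of 1 list, at the same limit of 0.05. They are not corrected for the 41 lists looked at, so they are more lenient than calls over all genes. Camera at the preset correlation sets the genes of a list against all other genes. Its p-values do not measure how a list as a whole varies between samples. The permutation p-values given further below resample genes, not samples. Hexokinases (2 measured members), endothelial markers (1), immune cell markers (1) and xenobiotic metabolism (4) were too small to test. The genes named in the report were chosen by a rule set before the data were examined. It took, per comparison, the 12 largest rises and the 12 largest falls among called genes whose groups of 3 libraries did not overlap. Where fewer than 6 passed in a direction, the lowest-p genes up to 6 were given as values. It also took the hexokinases, up to 4 lowest-p members of each list, and 10 genes called in both comparisons in opposite directions, of which there were none. HK1, HK3 and HKDC1 are not among the rows, so HK2 was the measured hexokinase, and the knockdown, made in the donor cells, was not checked here. Some genes that the rule names are not reported here.

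The gene and list tests were tested on simulated data with 200 changed genes. For ectosome against control, on 9930 genes, 74% of 1.25-fold and 94% of 1.5-fold changes were called, and 11 unchanged genes. For HK1-KD ectosome against ectosome, on 9930 genes, 72% of 1.25-fold and 88% of 1.5-fold changes were called, and 9 unchanged genes. For HK1-KD ectosome against control, on 9931 genes, 72% of 1.25-fold and 100% of 1.5-fold changes were called, and 12 unchanged genes. A list of 24 genes shifted by 1.15-fold was called in each of the 3 comparisons. The simulated libraries shared 1 average spread per expression level, so an outlying library was not represented. Differences in spread between genes of similar level were not represented either. The shares called therefore do not show what share of such changes would be called in the real data. The simulated genes were drawn independently of each other, so correlation between the genes of a list was not represented either. The call of the shifted list therefore does not show how camera at the preset correlation treats correlated lists. In the real data all 9 replicate pairs differed by more than sampling noise, with a chi-square per gene between 2.28 and 8.55, so no pair was merged.

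Alternatives were other pseudocounts, filters, scalings and spread models, a replicate block, other sample sets, and each replicate left out. Limma's voom on the recovered reads, protein-coding genes only (8867 rows), a GC and length correction and, for lists, quantile normalization were added after the data were seen. Figures were drawn with matplotlib 3.10.9.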

Results

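The transcriptomes of 9 Huh7 hepatoma samples were compared: 3 controls, 3 incubated with stellate cell ectosomes, and 3 incubated with ectosomes from stellate cells with the hexokinase gene HK1 knocked down. The comparisons ask what the ectosomes changed in the recipient hepatoma cells and whether HK1 in the donor cells mattered for it. Values for 10000 genes were available in FPKM, normalised for gene length and library total by the authors. The values imply library totals of 20516698, 22150692 and 27230636 reads in the controls, 19969480, 17773140 and 22581073 in the ectosome samples, and 24239427, 21187226 and 21411649 in the HK1-KD ectosome samples.

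Ectosome-treated cells had higher levels of neutrophil-attracting chemokine transcripts than controls. CXCL5 rose from 26.6 ± 2.23 to 127 ± 8.53 FPKM (SD, n = 3 each), a log2 change of 2.21 (SE 0.068, adjusted p = 1.22e-05). CXCL1 rose by 2.11 (SE 0.078) and CXCL2 by 1.93 (SE 0.085) on the log2 scale, and CXCL6 and CXCL8 by 1.64 and 1.13. ICAM1, a leukocyte adhesion molecule, rose from 11.9 ± 0.622 to 33.3 ± 0.308 FPKM, and SOD2, the mitochondrial superoxide dismutase, from 7.07 ± 0.0702 to 16.1 ± 0.859 FPKM. Of the 15 measured members of the list of NF-kB and inflammatory cytokines, 14 were called higher and none lower; adjusted over the list alone, 15 were higher. The list's median log2 change was 0.64 (camera adjusted p = 1.07e-27; adjusted p = 0.0582 with an estimated correlation).

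The acute phase response, the set of plasma proteins that the liver makes in inflammation, moved with it. Of its 11 measured members 10 were called higher, and 11 when adjusted over the list alone, with a median log2 change of 0.52 (camera adjusted p = 9.76e-18; adjusted p = 0.0582 with an estimated correlation). CEBPD, a transcription factor of this response at chromosome 8, 47736909 to 47739086 on GRCh38, had the largest rise of all called genes with separate groups, from 2.67 ± 0.216 to 16.3 ± 2.25 FPKM (log2 change 2.23, SE 0.092). Complement C3 rose from 29.2 ± 1.23 to 81.4 ± 2.09 FPKM, and the iron hormone HAMP and the acute phase protein ORM1 rose by 0.85 and 0.89 on the log2 scale. AC008760.2, a single-exon noncoding RNA at chromosome 19, 6716386 to 6717742, rose by 2.19; it is annotated as sense-intronic within C3, on the same strand, so reads from unspliced C3 transcripts would count there too. Among interferon response genes, 5 of 10 were called higher and 7 when adjusted over the list alone, including DTX3L (log2 change 0.50) and CXCL10 (1.10). That list passed camera at an adjusted p of 7.64e-08 (adjusted p = 0.0582 with an estimated correlation).

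**Figure D1:**
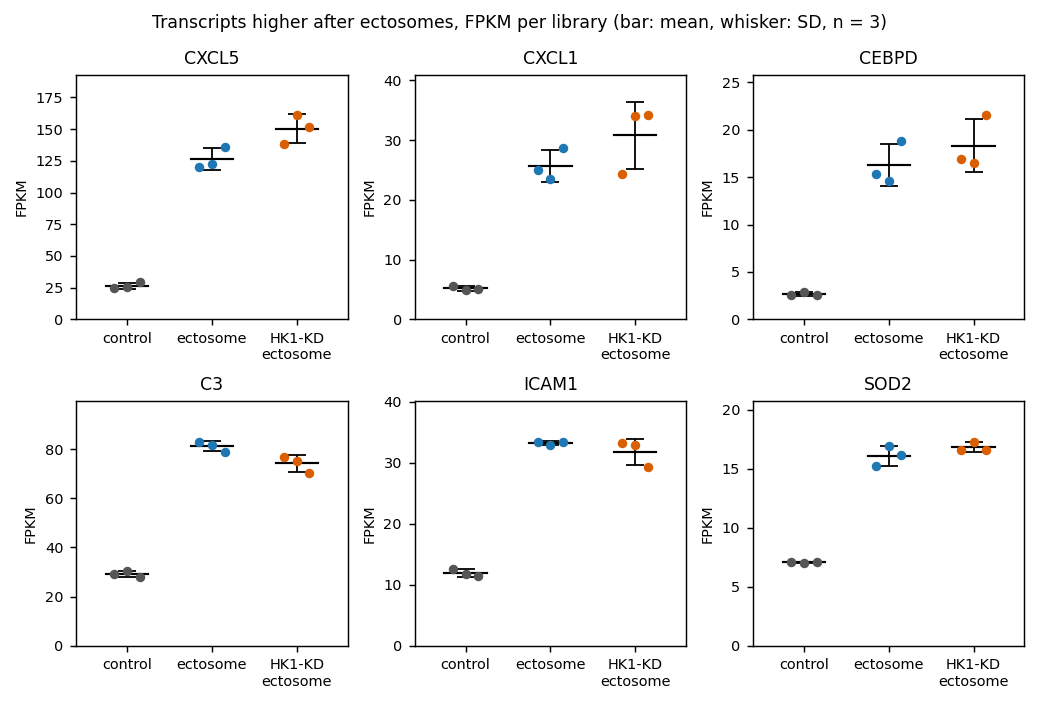
FPKM of 6 transcripts in each library, by group; points are libraries, bars are means and whiskers SD (n = 3). CXCL5 lies between 25.0 and 29.1 FPKM in the controls and between 121 and 136 FPKM in the ectosome libraries.

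Lipid synthesis genes were lower. In the list of cholesterol synthesis and SREBP2 targets, 12 of 24 members were called lower and none higher, and 16 were lower when adjusted over the list alone. INSIG1, a sterol-sensing regulator, fell from 55.2 ± 1.35 to 44.1 ± 1.21 FPKM; INSIG1 was not called in a fit of all 9 samples (adjusted p = 0.063). The list's median log2 change was −0.14 (camera adjusted p = 6.94e-13; adjusted p = 0.0582 with an estimated correlation). In the list of fatty acid synthesis and SREBP1 targets 4 of 15 were called lower and 8 when adjusted over the list alone, with ACSS2, an acetyl-CoA synthetase, at a log2 change of −0.33 (camera adjusted p = 1.13e-06; adjusted p = 0.219 with an estimated correlation). Hepatocyte secreted proteins went both ways and did not pass as a list (adjusted p = 0.241): 8 of 17 were called higher and 3 lower, and 8 were higher and 5 lower when adjusted over the list alone. TTR, a member, fell by 0.47 on the log2 scale, and outside the list APOA1 fell by 0.45 and the sterol esterifying enzyme SOAT2 by 0.64. The largest falls, in the small RNAs RNU6-7 (−1.33) and RNU7-3P (−1.28), are uncertain, since these small RNAs belong to multicopy families. Their values in the ectosome libraries were also low, at 0.468 to 1.24 FPKM for RNU6-7 and 1.43 to 4.04 FPKM for RNU7-3P. On transcripts this short such values rest on few reads. The call for RNU7-3P was lost without any 1 of the 3 controls and without ectosome replicate 2 or 3 (adjusted p of 0.096, 0.117, 0.0939, 0.0944 and 0.0912).

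Other lists passed too, among them some of the lists on energy metabolism and stress. Glycolysis genes were higher, with 5 of 17 called and 8 higher and 1 lower when adjusted over the list alone (camera adjusted p = 9.39e-06; adjusted p = 0.0582 with an estimated correlation). They included GPI (log2 change 0.24) and the lactate exporter SLC16A3 (0.53). The lists of nuclear-encoded oxidative phosphorylation (adjusted p = 0.874), the TCA cycle (0.795), the pentose phosphate pathway (0.967), gluconeogenesis (0.874), the heat shock response (0.373), NRF2 (0.254) and the ATF4 response (0.367) did not pass. HK2, the measured hexokinase, rose from 24.2 ± 0.627 to 29.8 ± 1.03 FPKM (log2 change 0.29, SE 0.036, adjusted p = 0.00652). Lists for the hypoxia response, the unfolded protein response, autophagy and lysosome, apoptosis regulators and mitochondrially encoded genes also passed upward (camera adjusted p = 5.35e-07, 3.63e-07, 8.79e-06, 0.018 and 5.35e-07). With an estimated correlation their adjusted p were 0.0951, 0.181, 0.216, 0.186 and 0.296. The lists of YAP/TAZ targets, G2/M and mitosis, Wnt targets, and serine, glycine and one-carbon metabolism passed downward (camera adjusted p = 0.000427, 0.00184, 0.0164 and 0.0349). With an estimated correlation their adjusted p were 0.181, 0.388, 0.238 and 0.216. The call was lost for G2/M and mitosis without ectosome replicate 3 (adjusted p = 0.0503) and for Wnt targets without ectosome replicate 2 (0.0657). The call for serine, glycine and one-carbon metabolism was lost without control replicate 2, ectosome replicate 1 or ectosome replicate 3 (at most 0.0934). The mitochondrially encoded list lost its call after quantile normalization (0.0723); mitochondrial genes held 18.6 to 19.2% of the FPKM sum in controls and 19.9 to 21.7% in ectosome samples. The TGF-beta response list did not pass (adjusted p = 0.967), although 4 of its 20 members were called higher, among them BHLHE40 (log2 change 0.65), and 1 lower; adjusted over the list alone, 4 were higher and 5 lower. Stellate cell and fibroblast markers did not pass either (adjusted p = 0.354); 2 of 11 were called higher, and adjusted over the list alone 2 were higher and 3 lower, COL1A2 reaching 3.31 ± 0.136 FPKM against 2.26 ± 0.0197 FPKM in controls.

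In total 476 of 10000 genes were called between ectosome and control samples, 292 higher and 184 lower (limma), of which 14 and 2 changed at least 2-fold. The 2 that fell this far were the uncertain small RNAs RNU6-7 and RNU7-3P. The 3 libraries of one group lay fully apart from those of the other for 24% of genes, against 10% by chance. Leaving out 1 library reduced the count to 183, 217 or 269 without control replicate 1, 2 or 3, and to 298 or 203 without ectosome replicate 1 or 3, while voom on the recovered reads called 873. Among the 15 lists that passed camera, none passed with an estimated correlation.

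The comparison of HK1-KD ectosome with ectosome samples asks what the knockdown in the donor cells changed in the recipient cells; HK1 itself was not analysed here. ACSS2 had the lowest p of all genes, at 7.93 ± 0.0503 against 10.3 ± 0.0985 FPKM (log2 difference −0.35, SE 0.032, adjusted p = 0.101). Other lipid synthesis genes with low p were FADS2, a fatty acid desaturase (45.5 ± 4.10 against 58.8 ± 1.37 FPKM), IDI1, an isoprenoid isomerase (36.8 ± 0.965 against 43.7 ± 1.54 FPKM), and MVD, a decarboxylase of the mevalonate pathway (63.1 ± 1.27 against 73.1 ± 2.57 FPKM), each with an adjusted p of 0.415. SERPING1, the inhibitor of complement C1, stood at 29.5 ± 1.23 against 37.3 ± 0.591 FPKM (log2 difference −0.33, adjusted p = 0.151). HBQ1, a globin gene, stood at 6.62 ± 0.400 against 3.86 ± 0.546 FPKM (adjusted p = 0.242). HK2 was at 26.8 ± 1.88 against 29.8 ± 1.03 FPKM (log2 difference −0.15, SE 0.055, adjusted p = 0.683). In total 0 of 10000 genes passed the test (limma), while 719 had an unadjusted p under 0.05 against 500 expected by chance, and groups were fully apart for 12.6% of genes against 10% by chance. Other fits called 1 gene with sample weights (ACSS2), 3 among protein-coding genes only and 3 in the fit of all 9 samples (ACSS2, SERPING1 and HBQ1 in both), and 7 with voom on the recovered reads, all lower.

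**Figure D2:**
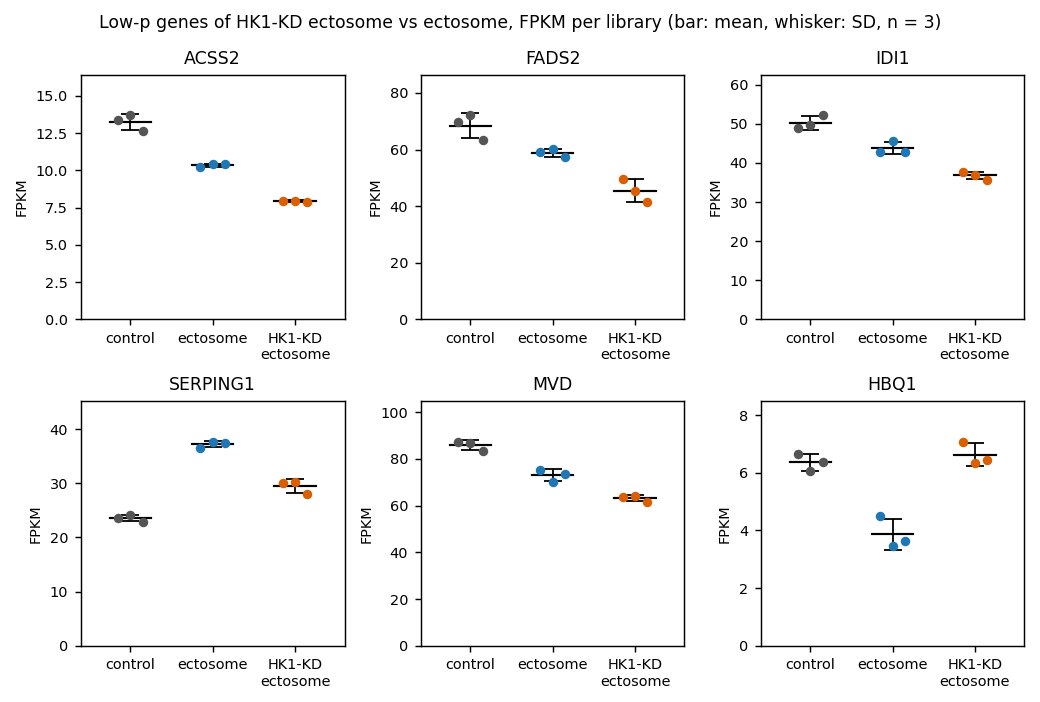
FPKM of 6 genes in each library, by group, chosen from the named genes with low p between HK1-KD ectosome and ectosome; points are libraries, bars are means and whiskers SD (n = 3). None passed the adjusted test between these groups. ACSS2 lies between 7.88 and 7.97 FPKM in the HK1-KD ectosome libraries and between 10.2 and 10.4 FPKM in the ectosome libraries.

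Among the gene lists, lipid synthesis and liver secretory genes had the lowest p. Camera passed 12 lists here, and 13 in another split of the same 6 samples that mixed the groups. The number of lists therefore does not set the real groups apart. Cholesterol synthesis and SREBP2 targets were lower with HK1-KD ectosomes: 23 of 24 members had a log2 difference below 0, the median was −0.16, and 19 passed when adjusted over the list alone (camera adjusted p = 4.97e-24; adjusted p = 0.109 with an estimated correlation). Fatty acid synthesis and SREBP1 targets were lower with a median of −0.21 (camera adjusted p = 5.68e-11, and 0.359 with an estimated correlation). Adjusted over the list alone, 10 members were lower and 1 higher. The list's level varied more between HK1-KD ectosome libraries (SD 0.097) than between ectosome libraries (SD 0.037). FADS2 stood at 49.5, 45.5 and 41.3 FPKM in HK1-KD ectosome replicates 1, 2 and 3, while ACSS2 stayed between 7.88 and 7.97 FPKM. Hepatocyte secreted proteins were lower with a median of −0.14 and 6 of 17 members lower when adjusted over the list alone (camera adjusted p = 1.03e-09; adjusted p = 0.109 with an estimated correlation). The acute phase response had a median of −0.13 (camera adjusted p = 0.00162, and 0.359 with an estimated correlation). Of its 11 members, 5 were lower when adjusted over the list alone. It overlaps the list of hepatocyte secreted proteins, at least in the fibrinogen gene FGB, so the falls of these lists are not separate results. The list of G1/S and DNA replication passed downward and that of autophagy and lysosome upward, with 0 members of either passing when adjusted over the list alone (camera adjusted p = 0.000859 and 0.000209; adjusted p = 0.575 for both with an estimated correlation).

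The other 6 of the 12 lists that passed camera lost their call when 1 library was left out. G2/M and mitosis (camera adjusted p = 0.000859, downward) was lost without HK1-KD ectosome replicate 3 (0.451). Oxidative phosphorylation, nuclear encoded (0.0026, upward) was lost without ectosome replicate 2 (0.0506). Unfolded protein response (0.0176, downward) was lost without ectosome replicate 2 or 3 or HK1-KD ectosome replicate 1, and after quantile normalization (at most 0.202). MYC and ribosome biogenesis (0.0444, downward) was lost without ectosome replicate 1 or 2 or HK1-KD ectosome replicate 3 (at most 0.335). NF-kB and inflammatory cytokines (0.0405, upward) and YAP/TAZ targets (0.0405, upward) were each lost without ectosome replicate 2, HK1-KD ectosome replicate 2 or HK1-KD ectosome replicate 3, and the NF-kB list also without ectosome replicate 1 and after the GC and length correction (at most 0.23 and 0.262). With an estimated correlation the adjusted p of these 6 lists were 0.594, 0.575, 0.575, 0.575, 0.584 and 0.575. Glycolysis did not pass camera (median −0.02, adjusted p = 0.0669), nor did the pentose phosphate pathway (median 0.01, mean −0.02, adjusted p = 0.352). With fry, which does not compare a list with other genes, both passed downward (adjusted p = 0.0159 and 0.0126), as did the cholesterol synthesis and hepatocyte secreted protein lists (0.0126 each). On the first principal component the HK1-KD ectosome replicates 1, 2 and 3 formed a graded series at 2.43, 6.41 and 11.1. Replicate 1 lay within the range of the ectosome libraries (1.29 to 5.04). On the second, HK1-KD ectosome replicate 3 stood apart at −8.11 and ectosome replicate 2 at 9.56. Without either 1 of these libraries that stood apart 8 lists passed.

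**Figure D3:**
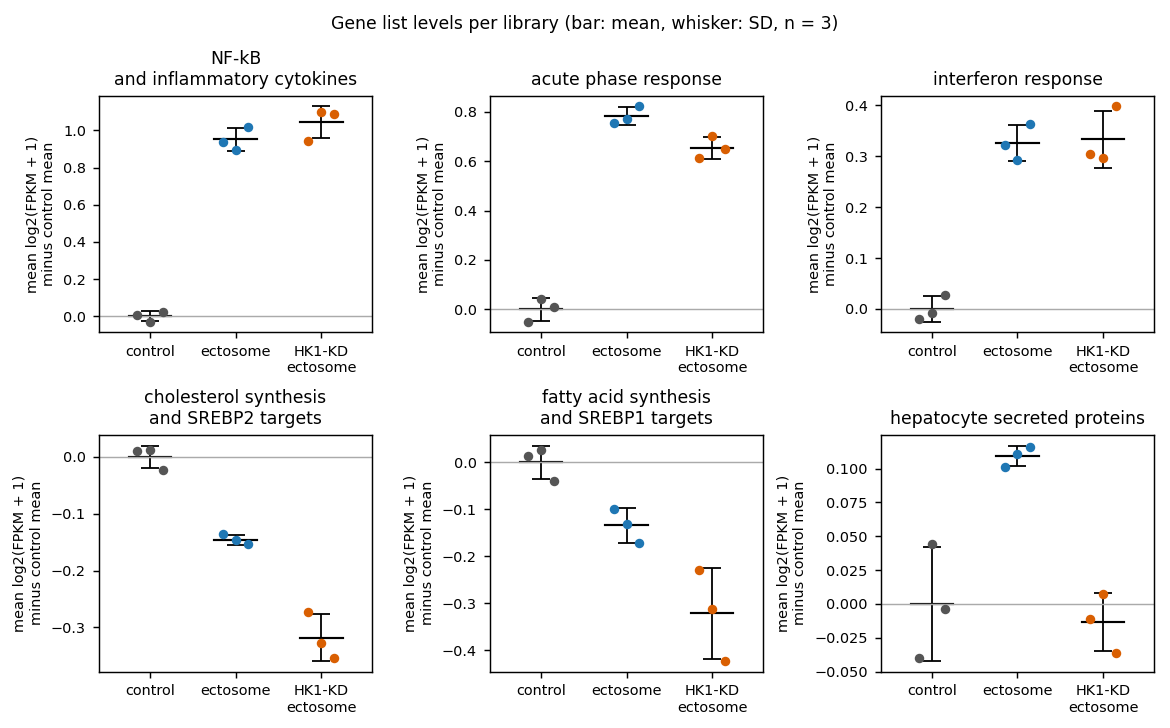
Mean log2(FPKM + 1) over the members of 6 gene lists in each library, minus the control mean; points are libraries, bars are means and whiskers SD (n = 3), and the axes differ in range. Cholesterol synthesis genes lie at −0.15 ± 0.009 in the ectosome group and −0.32 ± 0.041 in the HK1-KD ectosome group.

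Against controls, HK1-KD ectosome samples showed the inflammatory rise as well. CXCL5 reached 150 ± 11.2 FPKM (log2 change 2.46, SE 0.073, adjusted p = 5.32e-07), CEBPD 18.3 ± 2.79 FPKM (2.39, SE 0.111) and ICAM1 31.8 ± 2.11 FPKM (1.34, SE 0.050). For NF-kB and inflammatory cytokines 14 of 15 members were called higher, and 15 when adjusted over the list alone; for the acute phase response 9 of 11 were called higher, and 9 over the list alone. Cholesterol synthesis and SREBP2 targets were called lower in 21 of 24 members, and in 23 when adjusted over the list alone, with a median log2 change of −0.30. IDI1 fell by 0.44, MSMO1, a sterol oxidase, by 0.44 and INSIG1 by 0.71 on the log2 scale. INSIG1 was graded over HK1-KD ectosome replicates 1, 2 and 3, at 38.6, 33.1 and 29.3 FPKM. For fatty acid synthesis and SREBP1 targets 12 of 15 were called lower, and 13 over the list alone; ACSS2 fell by 0.68 (SE 0.034, adjusted p = 4.87e-06). The NF-kB, acute phase and cholesterol lists passed camera at adjusted p of 1.31e-23, 3.29e-09 and 1.31e-23, and were the 3 that passed with an estimated correlation (adjusted p = 0.0288 each). The fatty acid list passed at 1.56e-12 (adjusted p = 0.0965 with an estimated correlation). The interferon response (7 of 10 members called higher, 8 over the list alone) and autophagy and lysosome (13 of 27 higher, 15 over the list alone) passed at 4.11e-07 and 9.58e-07 (adjusted p = 0.0899 and 0.258 with an estimated correlation). Glycolysis also passed upward, at 0.00308 (adjusted p = 0.0899 with an estimated correlation), with 3 of 17 members called higher, and 3 higher and 1 lower over the list alone. HK2 was not called (log2 difference 0.14, SE 0.050, adjusted p = 0.123). The mitochondrially encoded list passed camera upward (adjusted p = 3.6e-05, and 0.365 with an estimated correlation), with 6 of 13 members called higher. Its call was lost after quantile normalization (0.0586), and mitochondrial genes held 20.0 to 20.9% of the FPKM sum. Stellate cell and fibroblast markers did not pass camera (adjusted p = 0.0787), with 4 of 11 called higher and 2 lower.

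In total 936 genes were called, 561 higher and 375 lower (limma), and 17 of 41 lists, 11 upward and 6 downward. These counts come from the fit of all 9 samples and are not to be set against the 476 genes and 15 lists of ectosome against control, fitted on 6. On the 6 samples of its 2 groups HK1-KD ectosome against control called 727 genes. In the fit of all 9 samples ectosome against control called 406. After median centring the split was 469 higher and 489 lower. The count was 475, 432 or 594 without control replicate 1, 2 or 3, and 486 or 507 without HK1-KD ectosome replicate 2 or 3. Genes called in both comparisons with the controls numbered 246 higher and 147 lower, where independent lists would share 16.4 and 6.9 and simulated unchanged groups on the same controls shared 0 and 0.01 on average. The 3 controls could not be split into parts of at least 2 libraries each, so part of this excess may come from the shared controls. The log2 changes of both comparisons had a covariance across genes of 0.01863, against 0.00322 in the simulated groups. Since 0 genes were called between HK1-KD ectosome and ectosome, the count of genes called in opposite directions in that comparison and in ectosome against control was fixed at 0, as was the value for independent lists; simulation of unchanged groups also gave 0. Across genes, which are not independent replicates, the log2 changes of these comparisons had a covariance of −0.00284, against −0.00326 in simulated unchanged groups that shared the ectosome libraries.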

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

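Voom on the recovered reads, protein-coding genes only, the GC and length correction and quantile normalization for lists were chosen after the data were examined; the other alternatives were planned. Between ectosome and control, 476 called genes became 16 with a fold limit of 2, 873 with voom and 884 with voom and median-of-ratios scaling, and 183 to 386 with 1 library left out. The 15 lists became 0 with an estimated correlation. Between HK1-KD ectosome and ectosome, 0 called genes became 1 with sample weights, 7 with voom, 7 with voom and median-of-ratios scaling, 3 among protein-coding genes and 3 in the fit of all 9 samples, and stayed at 0 with any 1 library left out. The 12 lists became 0 with an estimated correlation and 4 with fry, of which 2 were shared. Between HK1-KD ectosome and control, 936 called genes became 1715 with sample weights, 18 with a fold limit of 2, 1425 with voom and 1457 with voom and median-of-ratios scaling, and 432 to 1247 with 1 library left out. The 17 lists became 3 with an estimated correlation. Genes called in opposite directions in the comparisons that share the ectosome samples numbered 0, but 3 with voom and 3 with voom and median-of-ratios scaling (SERPING1 and C5 among them), 2 among protein-coding genes and 2 in the fit of all 9 samples (SERPING1 and HBQ1). C5 was named after its values were seen. A fold limit, a smaller gene set and fewer samples change counts by construction; the cause of the other moves was not tested. Among the named genes called in ectosome against control (105) and in HK1-KD ectosome against control (134), none reversed its sign in an alternative. Without control replicate 1, 49 of the 105 and 49 of the 134 lost their call. Named genes that were not called, which include all those of HK1-KD ectosome against ectosome, were left out of this tally. Same-numbered samples had correlations of 0.01 to 0.16, all above 0, against −0.13 to 0.08 for samples of different number. Of 9 samples, 6 correlated best with their own number. The main fits did not take the numbers as pairs, and a pairing by number stays open. A replicate block gave 372, 0 and 1025 called genes and 16, 17 and 18 lists for the 3 comparisons. The other alternatives left each count within 1.5 times; leaving out the filter changed nothing, since it removed no row. The count models planned in case reads could be recovered were not run, although reads were recovered for the matched rows. Voom on these reads was added instead. The median row held 798 or more reads in every library, so depth limits the low rows most.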

Other observations

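The lists of complement, MHC class I and antigen processing, intestinal epithelium and LXR target genes were chosen after the data were examined, as were the test of cholesterol genes without HK1-KD ectosome replicate 3 and the splits of the samples for genes. Adjusted p for these 4 lists were taken over 45 lists, the 41 tested ones included; since the lists were picked from these data, their p are too small and not to be set against those of the planned lists. C5, B2M, CDH17 and VIL1 were named after their values were seen. Complement genes were higher in ectosome than in control samples: 7 of 14 were called higher and none lower, with a median log2 change of 0.24 (camera adjusted p = 9.16e-09; adjusted p = 0.0456 with an estimated correlation). C5 rose from 19.5 ± 0.548 to 36.0 ± 1.12 FPKM (SD, n = 3 each). For MHC class I and antigen processing 2 of 11 genes were called higher, and all 11 had a log2 change above 0 (camera adjusted p = 2.03e-06; adjusted p = 0.0456 with an estimated correlation); B2M, the light chain of MHC class I, rose by 0.27 on the log2 scale. Of 7 intestinal epithelium genes 6 were called lower (camera adjusted p = 2.84e-07; adjusted p = 0.124 with an estimated correlation), including the cadherin CDH17, which fell by 0.35, and the microvillus protein VIL1, which fell by 0.39 on the log2 scale.

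For the first pattern, the rise of the NF-kB list with ectosomes, RNA carried over from stellate cells would bring that cell type's abundant transcripts. The 11 stellate markers gained a median of 0.854 FPKM against 8.74 FPKM for the 15 NF-kB genes (permutation p = 0.0022, two-sided). That p cannot decide the question, because 1 of its lists is the one whose rise was to be explained. RNA of the stellate cells or of the ectosomes was not among the samples, so which transcripts would be carried over is unknown. Some markers had higher means with ectosomes, such as S100A6 (32.3 to 38.4 FPKM), LOXL2 (2.87 to 4.15 FPKM) and COL1A2 (2.26 to 3.31 FPKM). Others, already high in the controls, had lower means, such as VIM (104 to 94.6 FPKM) and CALD1 (75.9 to 68.7 FPKM). Carry-over therefore stays open. Read depth is argued against as the whole cause, because 13 of 15 members were called after every library was thinned to the smallest total. Other material in the pellet, such as serum particles, cannot be told apart from ectosomes, since 0 groups received a pellet without ectosomes, and a response to ectosomes stays a hypothesis.

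The second pattern is the lower cholesterol synthesis list with HK1-KD ectosomes. Without HK1-KD ectosome replicate 3, 1 of the libraries that stood apart, the median log2 difference was −0.159 (unadjusted camera p = 3.08e-27; unadjusted p = 0.00791 with an estimated correlation, against 0.00533 with all libraries, which is 0.109 when adjusted and does not pass). After correction for GC content and gene length it was −0.184 (unadjusted camera p = 2.6e-27; unadjusted p = 0.00802 with an estimated correlation), so neither was the whole cause. A higher sterol load may lower this list and would raise LXR targets; their median was −0.014 with 2 of 6 above 0. The bound set beforehand, a median at or below 0, was met, but by less than the spread of members that go both ways, so sterol load stays open; that the spread decides was settled after the median had been seen. An effect of the donor knockdown stays open as well, and no single gene of this list passed limma on log2 FPKM when adjusted over all 10000 genes (19 of 24 did over the list alone), while HMGCS1 and IDI1 did with voom (adjusted p = 0.0338 each).

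The third pattern is the lower level of complement genes with HK1-KD ectosomes, which had a median of −0.10 over 14 genes (camera adjusted p = 9.75e-07; adjusted p = 0.292 with an estimated correlation). Without HK1-KD ectosome replicate 3 the median was −0.088 (unadjusted camera p = 3.86e-09; unadjusted p = 0.0082 with an estimated correlation, against 0.0195 with all libraries), which argues against that library alone. The pattern may be part of a wider fall of hepatocyte secreted protein transcripts: the 13 complement genes outside that list had a median of −0.114 and the 16 secreted protein genes outside the complement list −0.14 (permutation p = 0.5, two-sided). That p does not show the lists to be equal.

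Only 10 splits of 6 samples exist, too few for a share under 0.05. Between ectosome and control, the real split called 476 genes and the highest other 0, so 1 split was as large; for lists the numbers were 15, 11 and 1. Between HK1-KD ectosome and ectosome, the real split called 0 genes and the highest other 1, so all 10 splits were as large; for lists the real split gave 12 and the highest other 13, so 2 splits were as large. Between HK1-KD ectosome and control, in fits of all 9 samples for every split, the real split called 936 genes and the highest other 0, so 1 split was as large; for lists the numbers were 17, 16 and 1.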
